A study of Drosophila melanogaster with 16 samples.

How the data were processed

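Total RNA of female midguts was extracted with TRIzol, labelled with biotin by a 3' in vitro transcription kit and hybridised to Affymetrix Drosophila Genome 2.0 arrays, per the labels. The deposited values are RMA signals on the log2 scale, made by the authors for 18952 probe sets on 16 arrays. The RMA software and its version are not given in the sources used here. Values ran from about the same floor to the same ceiling on every array, as RMA gives, and no further normalisation was applied. Each array is one column, and 183 Affymetrix control probe sets were set aside, which left 18769 probe sets for testing.

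Probe sets were joined to gene symbols with the supplied table of probe genes. Of the tested probe sets, 13647 had 1 symbol, 402 had several and 4720 had none. The probe set with the highest mean over the 16 arrays stood for its gene among those with 1 symbol, which gave 11982 genes for the named genes and the gene lists. Counts of probe sets used all 18769.

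Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 16 arrays (12 residual degrees of freedom), default empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison. A probe set was called at an adjusted p under 0.05, two-sided. Each SE of a change is the moderated one of this fit. It rests on the spread over all 16 arrays, not only on the groups compared. The 4 main comparisons were RafGOF minus wild type, RafGOF NotchDN minus RafGOF, RafGOF NotchIC minus RafGOF, and RafGOF NotchDN minus RafGOF NotchIC. Both Notch groups were also compared with wild type. The p-values measure only the spread between arrays, since the labels do not say whether the arrays of a group come from separate animals, pools or crosses. The number of arrays limits the precision.

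The 30 gene lists cover cell types, pathways and complexes of the gut and of tissues that a dissection can carry along. Each was tested with limma camera at a preset correlation between genes of 0.01, with adjustment over the 30 lists in each comparison. Of 673 list entries, 562 were measured. No probe set was named for the Notch targets E(spl)m8-HLH and E(spl)mgamma-HLH. The same held for pnt, rho and vn of the EGFR list and for upd3, hop and Socs36E of the JAK/STAT list. The mean signal of the Notch target list was 5.12 to 5.66 (log2) by group, about at or below the array medians. A list that did not pass therefore does not show that its pathway did not respond. With the correlation estimated from the data, no list passed in any main comparison, so that p stands beside each list. Median, mean and test had one direction for every list that passed in the main comparisons. They differed in direction for 1 list that did not pass in RafGOF minus wild type, 8 in NotchDN over RafGOF, 6 in NotchIC over RafGOF and 1 between the Notch groups. The lists, comparisons, tests, the rule for named genes and the alternatives were fixed before the data were examined.

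The rule for named genes took, in each main comparison, the 5 largest rises and the 5 largest falls among called genes whose 4 arrays of one group all lay beyond the 4 of the other. Symbols made only of a CG or CR number were skipped, which passed over 2 rises and 2 falls in RafGOF minus wild type, 1 and 2 in NotchDN over RafGOF, 4 and 0 in NotchIC over RafGOF, and 0 and 4 between the Notch groups. From each list it then took up to 4 called members in order of size, or all where 5 or fewer passed. Members that did not pass could be named in the progenitor, Notch target, enteroendocrine and EGFR lists. Raf and Notch themselves were to be named first, but no probe set carries either symbol alone. The lists were shortened for RafGOF minus wild type, and this was decided after the values were seen. There the first 4 called members were named in the cell cycle, progenitor, EGFR, Notch target, digestive enzyme, enterocyte identity and enteroendocrine specification lists and the first 2 in the others. Another probe set of a named gene is given where its mean was at log2 5 or above and its call differed, or its change differed by over 1 (log2), which was also decided after the values were seen. The members named without passing, and klu between the Notch groups, were also chosen after their values were seen.

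Whether the replicate numbers in the labels pair the arrays was checked on the deviations from the group means, before the fits were compared. The labels do not say what a number stands for. Deviations of same-numbered arrays correlated at 0.127 to 0.594 for RafGOF and wild type, at 0.494 to 0.785 for NotchDN and RafGOF, at 0.104 to 0.528 for NotchIC and RafGOF, at 0.157 to 0.529 for NotchDN and NotchIC, and at 0.155 to 0.668 for NotchDN and wild type. By a minimum of 0.1 the numbers paired the arrays in these 5 comparisons, but not for NotchIC and wild type (0.0489 to 0.574). Of the 24 correlations, 8 were below the highest of the same arrays with another number. A fit with the replicate number as a block was an alternative. The main fit, fixed beforehand, does not use the numbers, and counts, calls and the choice of named genes rest on it unless another fit is named.

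The alternatives were median centring and a further quantile normalisation, a filter keeping probe sets at log2 5 or above on at least 4 arrays, trended and robust moderation, array weights, the replicate block, only the 8 arrays compared, 1 probe set per gene, the mean of all probe sets of a gene, stricter thresholds, each array left out in turn, camera with an estimated correlation and fry. A fit without the 4 arrays numbered 2 was added after seeing the data. Splits of the 8 arrays of each comparison were enumerated, and exact permutation tests were two-sided. The model was also tested on simulated data with 200 changed probe sets, with independent noise and with noise shared by replicate number. With independent noise it recovered 91% of 2-fold and 41% of 1.41-fold changes for RafGOF minus wild type, and 92% and 34% for NotchDN over RafGOF. With shared noise it recovered 91% and 34% of them for RafGOF minus wild type (95% and 57% with the replicate block), and 92% and 37% for NotchDN over RafGOF (97% and 66% with the block). It called 0 to 9 unchanged probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.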

Results

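RNA of the female Drosophila midgut was measured on 16 Affymetrix Drosophila Genome 2.0 arrays in 4 groups of 4 arrays. The groups were wild type, RafGOF, RafGOF with NotchDN, and RafGOF with NotchIC. By their names these are flies with a gain-of-function form of the kinase Raf, alone or together with a dominant-negative or an intracellular, active form of the receptor Notch. The series title places the study in intestinal stem cells, while the labels give whole midgut as the tissue. Median signal per array lay between 5.47 and 5.69 (log2), and pairs of arrays of one group correlated across probe sets at 0.979 to 0.995. The number of arrays limits the precision of every value below. No probe set was assigned the symbol of Raf or of Notch by itself, so neither manipulated gene is given a value. That Notch was blocked or active, as written below, rests on the group names.

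The arrays numbered 2 in the labels deviated together from their group means and stood apart from the rest. Their deviations correlated at 0.528 to 0.726 between groups, and those of the other same-numbered arrays at 0.0489 to 0.785. The highest of all was that of replicate 1 of RafGOF and RafGOF NotchDN. The first component of the deviations held 34.0% of their variance, with scores of 0.411 to 0.445 on the arrays numbered 2 and scores of -0.224 to -0.0347 on all others. The second held 22.4% and did not set the arrays numbered 2 apart. Its scores were 0.498 on RafGOF replicate 1 and 0.513 on RafGOF NotchDN replicate 1. They were -0.434 and -0.335 on replicate 4 of the same groups, and -0.309 to 0.215 on all other arrays. The 3' minus 5' difference of added control RNAs, which do not come from the flies, was 2.87 to 3.61 on the arrays numbered 2 and 1.33 to 2.30 on the others for phe. It was 1.32 to 2.14 against 0.30 to 1.28 for lys, 1.57 to 2.26 against 2.20 to 3.18 for thr and 2.41 to 3.36 against 2.22 to 4.03 for dap. Of these 4 RNAs, phe and lys were thus higher on the arrays numbered 2, while thr lay mostly lower and dap did not stand apart. In the 18S rRNA control probe set the 3' signal was 7.32 to 8.97 on the arrays numbered 2. It was 8.91 to 10.23 on those numbered 1, 10.95 to 12.82 on those numbered 3 and 11.63 to 12.43 on those numbered 4.

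**Figure D1:**
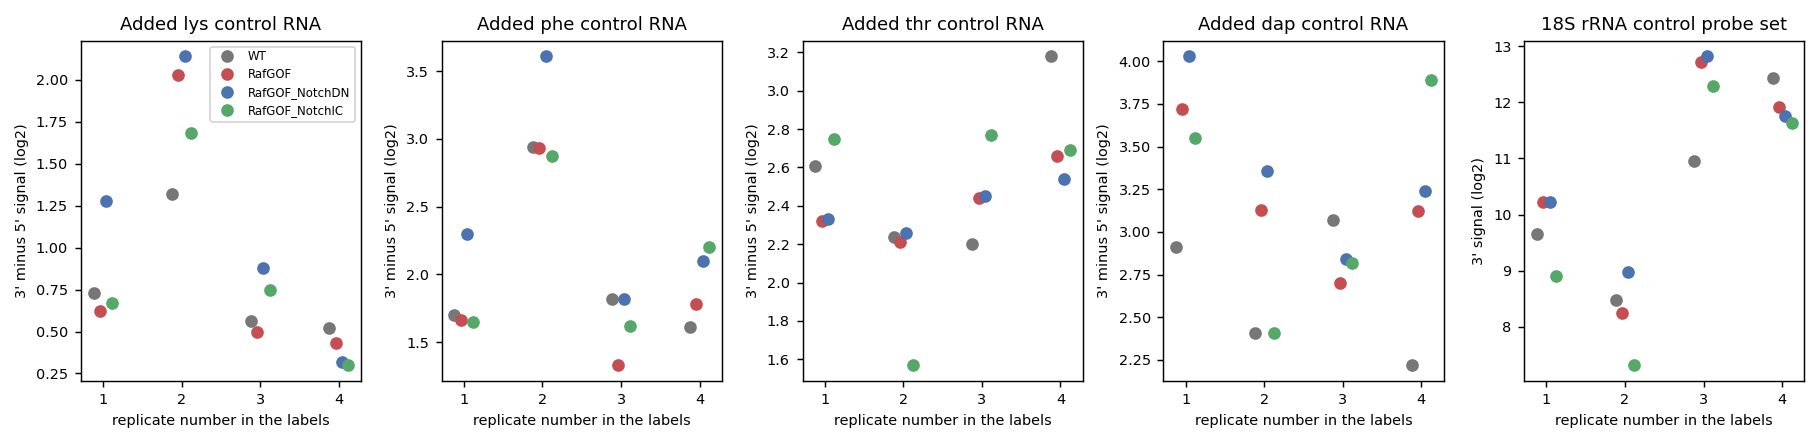
Each point is one array, placed by the replicate number in its label and coloured by group. The first 4 panels give the 3' minus 5' signal (log2) of the added lys, phe, thr and dap control RNAs, of which lys and phe were highest on the arrays numbered 2. The last panel gives the 3' signal of the 18S rRNA control probe set (log2), which lay between 7.32 and 12.82.

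RafGOF was compared with wild type to ask what active Raf changed in the midgut. Most of the measured cell cycle and progenitor genes rose, and most digestive enzyme genes fell. PCNA, the sliding clamp of DNA replication, rose by 2.71 ± 0.199 (log2, SE, n = 4 arrays per group), a 6.56-fold difference. The signal of esg, a transcription factor of intestinal stem cells and enteroblasts, was 7.86 ± 0.32 (SD, n = 4) in wild type and 10.36 ± 0.57 in RafGOF. LManIII, a lysosomal-type mannosidase, went from 10.97 ± 0.49 to 4.92 ± 0.28. Among genes whose 4 arrays of one group all lay above the 4 of the other, the largest rises (log2) were Rnf11 (3.51), betaTub60D (3.51), Pen (3.46), cher (3.41) and E(spl)m3-HLH (3.39). The largest falls were LManIII (-6.05), Ser8 (-4.61), Jon25Bii (-4.26), tobi (-4.18) and Cyp4d1 (-3.92). On its other probe set Rnf11 rose by 1.71. The adjusted p of these 10 genes ran from 2.87e-08 to 0.000107. In all, 2104 probe sets were higher and 1474 lower in RafGOF at an adjusted p under 0.05, of 18769 tested, and 552 and 592 of these differed by at least 2-fold. With the replicate number as a block the counts were 3220 higher and 2289 lower.

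**Figure D2:**
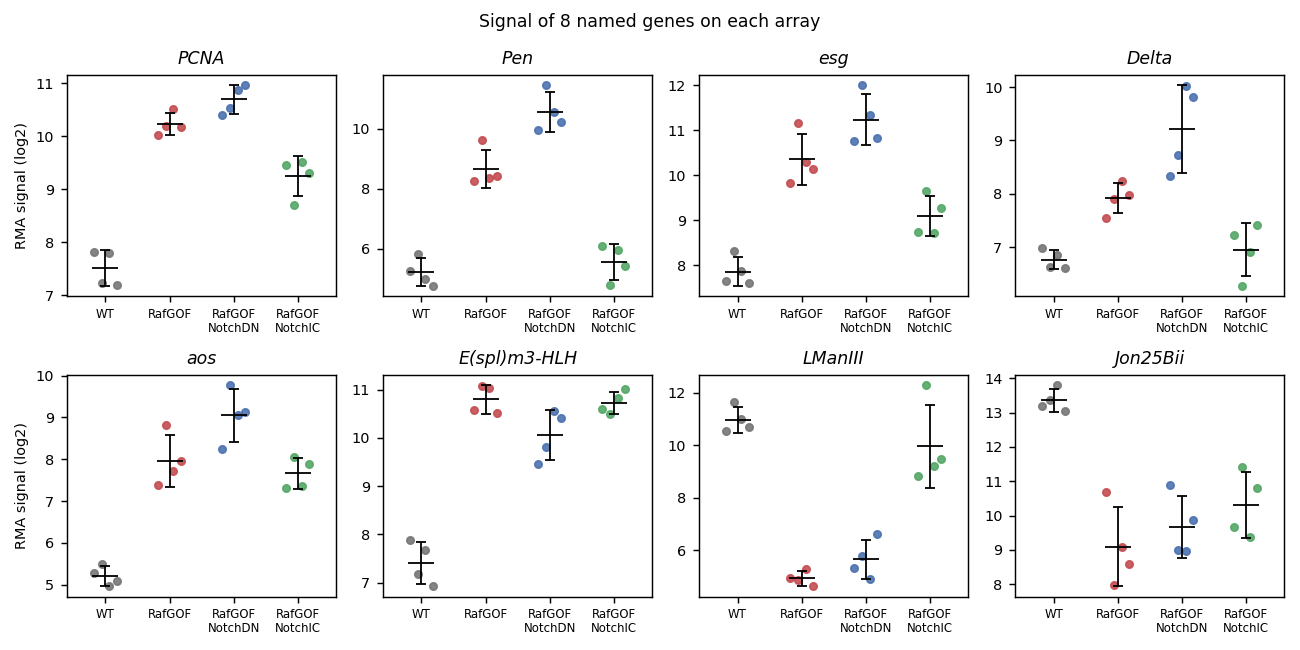
RMA signal (log2, vertical axis) of 8 named genes in the 4 groups, with one point per array, the group mean as a bar and the SD as the error bar (n = 4). PCNA and esg were higher in RafGOF than in wild type on every array, and LManIII and Jon25Bii were lower on every array.

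Of the 32 cell cycle genes, 27 rose (30 adjusted over the list alone) and 5 did not pass, led by borr (3.02), PCNA (2.71), CycE (2.51) and RnrL (2.30). The cell cycle list had adjusted p = 7.68e-17, and adjusted p = 0.187 with an estimated correlation. borr is a subunit of the chromosomal passenger complex, CycE drives entry into S phase and RnrL makes deoxynucleotides. Of the 23 ribosome biogenesis genes, 12 rose (13 adjusted over the list alone, 19 with the replicate block) and 11 did not pass, led by Surf6 (1.61) and Nph (1.49). The ribosome biogenesis list had adjusted p = 4.31e-08, and adjusted p = 0.214 with an estimated correlation. Of the 41 genes in the ribosomal protein list, 8 rose and 0 fell (13 and 0 adjusted over the list alone, 15 and 1 with the replicate block), and 33 did not pass, led by RpLP0-like (0.87) and RpL34a (0.62). The symbol of RpLP0-like marks a gene resembling RpLP0, not RpLP0 itself. The ribosomal protein list had adjusted p = 0.000256, and adjusted p = 0.409 with an estimated correlation.

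Of the 10 progenitor genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), and 3 did not pass, with esg (2.49), Sox100B (2.27), mira (-1.57) and Delta (1.15) the most changed. The progenitor list had adjusted p = 0.00785, and adjusted p = 0.244 with an estimated correlation. Delta is the Notch ligand of intestinal stem cells, and mira encodes an adaptor of asymmetric division. Of the 13 EGFR pathway genes, 7 rose (7 adjusted over the list alone) and 6 did not pass, led by aos (2.76), edl (2.56), Mkp3 (1.98) and spi (1.92). The EGFR pathway list had adjusted p = 0.000256, and adjusted p = 0.192 with an estimated correlation. Here aos is a secreted EGFR inhibitor, Mkp3 an ERK phosphatase and spi an EGFR ligand. Of the 14 Notch target genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), and 10 did not pass, the 4 that passed being E(spl)m3-HLH (3.39), E(spl)malpha-BFM (1.81), E(spl)mbeta-HLH (1.24) and E(spl)m6-BFM (-0.28). The Notch target list had adjusted p = 0.255, and adjusted p = 0.567 with an estimated correlation, and did not pass. Of the 13 enteroendocrine specification genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone), and 9 did not pass, the 4 that passed being sc (0.96), Ptx1 (-0.90), pros (-0.85) and tap (-0.75). The enteroendocrine specification list had adjusted p = 0.174, and adjusted p = 0.433 with an estimated correlation, and did not pass.

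Of the 47 digestive enzyme genes, 1 rose and 31 fell (2 and 36 adjusted over the list alone), and 15 did not pass, with a list median of -1.46. The digestive enzyme list had adjusted p = 4.41e-13, and adjusted p = 0.187 with an estimated correlation. Besides LManIII, Ser8 and Jon25Bii, the serine protease gene Jon44E fell by 3.72. Of the 10 enterocyte identity genes, 2 rose and 2 fell (4 and 2 adjusted over the list alone), and 6 did not pass, the 4 that passed being mag (-1.70), Ssk (0.89), cora (0.89) and Smvt (-0.75). The enterocyte identity list had adjusted p = 0.39, and adjusted p = 0.556 with an estimated correlation, and did not pass. Ssk and cora encode septate junction proteins and mag a lipase. Of the 18 lipolysis and fatty acid oxidation genes, 1 rose and 9 fell (1 and 10 adjusted over the list alone), and 8 did not pass, led by Lip3 (-2.23) and Acox57D-d (-1.66). The lipolysis and fatty acid oxidation list had adjusted p = 0.000256, and adjusted p = 0.187 with an estimated correlation. Of the 15 lipid synthesis genes, 5 fell (5 adjusted over the list alone) and 10 did not pass, led by Dgat2 (-1.12) and Agpat3 (-0.92). The lipid synthesis list had adjusted p = 0.0115, and adjusted p = 0.244 with an estimated correlation. Of the 12 glycolysis genes, 5 fell (6 adjusted over the list alone) and 7 did not pass, led by Pdk (-1.19) and Hex-C (-1.10). The glycolysis list had adjusted p = 0.00378, and adjusted p = 0.192 with an estimated correlation. Of the 31 V-ATPase genes, 9 fell (16 adjusted over the list alone, 19 with the replicate block) and 22 did not pass, led by Vha100-5 (-1.25) and Vha44 (-0.74). The V-ATPase list had adjusted p = 8.83e-05, and adjusted p = 0.187 with an estimated correlation.

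Lists of visceral muscle, Malpighian tubule, and matrix and integrin genes were measured as well. Of these, the Malpighian tubule list stands for a separate tissue that a dissected midgut can carry. Of the 16 visceral muscle genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone), and 5 did not pass, with Zasp52 (1.30) and Obsc (-0.93) the most changed and a list median of -0.67. The visceral muscle list had adjusted p = 6.64e-05, and adjusted p = 0.187 with an estimated correlation. Of the 10 Malpighian tubule genes, 3 fell (4 adjusted over the list alone, 6 with the replicate block) and 7 did not pass, led by Oatp58Db (-1.47) and Prestin (-1.21). The Malpighian tubule list had adjusted p = 0.00447, and adjusted p = 0.382 with an estimated correlation. Of the 20 matrix and integrin genes, 9 rose (10 adjusted over the list alone) and 11 did not pass, led by scb (2.73) and Mmp2 (2.35). The matrix and integrin list had adjusted p = 0.00738, and adjusted p = 0.382 with an estimated correlation. Without RafGOF replicate 4 the matrix and integrin list was lost (adjusted p = 0.0603).

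The other 17 lists did not pass in RafGOF against wild type, the Notch target, enteroendocrine specification and enterocyte identity lists among them, and the lowest adjusted p among them was 0.0694. Without RafGOF replicate 4 the antimicrobial and IMD (adjusted p = 0.00817), enteroendocrine peptide (0.0289) and hemocyte (0.0378) lists passed. Without WT replicate 3 the antimicrobial and IMD (0.0308) and fat body (0.0309) lists did. The gut region list passed without WT replicate 1 (0.0364) and the JAK/STAT list without RafGOF replicate 1 (0.0392). Of the 16 antimicrobial and IMD genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone), and 11 did not pass, with Drsl3 (2.89) and PGRP-SC2 (-1.97) the most changed. Of the 20 enteroendocrine peptide genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone), and 14 did not pass, with ITP (2.12) and CCHa2 (-1.30) the most changed. The enteroendocrine peptide list passed with the replicate block, downward (adjusted p = 0.0436), but with the block and an estimated correlation no list passed (lowest adjusted p = 0.172). Of the 13 gut region genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone), and 7 did not pass, with exex (2.20) and ct (-2.18) the most changed. Another ct probe set at a similar level was at -0.33 and did not pass (adjusted p = 0.508). Of the 20 stress and redox genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone), and 13 did not pass, with Prx6c (2.43) and GstD5 (-1.82) the most changed. Of the 8 JAK/STAT genes, 2 rose (2 adjusted over the list alone, 4 with the replicate block) and 6 did not pass, led by dome (1.31) and upd1 (0.82). Of the 9 Hippo genes, 3 rose and 0 fell (3 and 1 adjusted over the list alone), and 6 did not pass, led by kug (1.13) and ex (0.82). Of the 14 Wnt, Hedgehog and BMP genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, 4 and 2 with the replicate block), and 11 did not pass, with dpp (-0.84) and gbb (0.61) the most changed. Of the 7 COPI genes, 2 rose (2 adjusted over the list alone) and 5 did not pass, namely zetaCOP (1.48) and epsilonCOP (0.55). Of the 8 trachea genes, 3 fell (3 adjusted over the list alone) and 5 did not pass, led by Gasp (-0.71) and knk (-0.56). Of the 71 oxidative phosphorylation genes, 3 rose and 2 fell (0 and 1 adjusted over the list alone, 4 and 4 with the replicate block), and 66 did not pass, with COX7AL2 (-0.90) and ND-51L1 (-0.43) the most changed. Of the 11 fat body genes, 1 fell (1 adjusted over the list alone) and 10 did not pass, namely fon (-2.0). Of the 13 hemocyte genes, 1 fell (1 adjusted over the list alone, 3 with the replicate block) and 12 did not pass, namely NimC4 (-1.5). Of the 20 ovary and germline genes, 0 passed by limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05). Of the 7 heat shock genes, 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, 0 and 1 with the replicate block, 1 in all at an unadjusted p under 0.05), and 7 did not pass.

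Of the 74 genes named for RafGOF against wild type, 11 lost their call when single arrays were left out, with adjusted p up to 0.152. These were Delta, E(spl)m6-BFM, ND-51L1, Pdk, Prestin, Smvt, cora, dpp, epsilonCOP, kug and mag, and the number lost was 9 without WT replicate 4, 8 without RafGOF replicate 3 or RafGOF replicate 4, 7 without RafGOF replicate 2 or WT replicate 2 and 5 without WT replicate 1 or WT replicate 3.

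**Figure D3:**
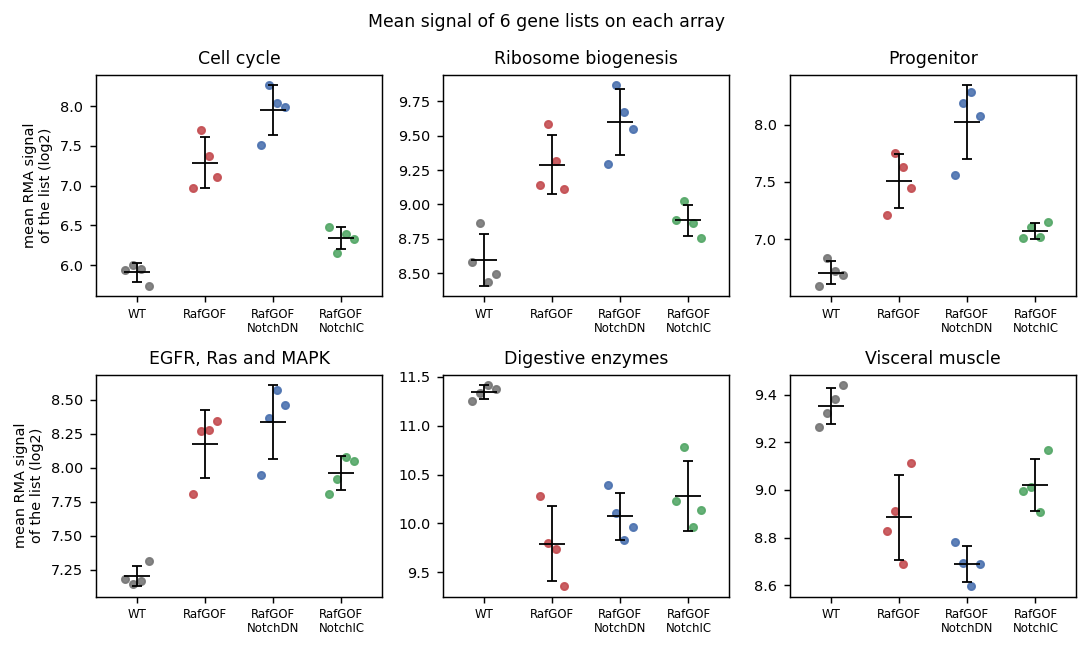
Mean RMA signal (log2, vertical axis) over the measured members of 6 gene lists in the 4 groups, with one point per array, the group mean as a bar and the SD as the error bar (n = 4). The cell cycle list was higher in each of the 3 RafGOF groups than in wild type on every array, and the digestive enzyme list was lower on every array.

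RafGOF with NotchDN was compared with RafGOF alone to ask what blocked Notch signalling changed in RafGOF midguts. Of the cell cycle genes 9 of 32 rose, and of the progenitor genes 2 of 10. Cks30A, which binds cyclin-dependent kinases, rose by 2.32 ± 0.209 (log2, SE, n = 4 arrays per group), a 5.01-fold difference. The largest rises were Drsl2 (2.80), Jon25Biii (2.69), Cks30A (2.32), Pen (1.89) and Cyp6a9 (1.67), and the largest falls were Erasp (-2.61), Cyp4p1 (-2.61), kon (-2.06), Cht2 (-2.0) and Prx6c (-1.73). Drsl2 is related to the antifungal peptide Drosomycin, and Pen is an importin. Not all of these genes were specific to blocked Notch. With NotchIC over RafGOF, Drsl2 (4.27), Jon25Biii (2.16) and Cyp6a9 (2.13) rose too, and Cyp4p1 (-1.8) and Prx6c (-1.33) fell too. Cks30A and Pen went the other way there. In all, 121 probe sets were higher and 83 lower, 58 and 29 of them by at least 2-fold.

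Of the 32 cell cycle genes, 9 rose and 0 fell (16 and 1 adjusted over the list alone), and 23 did not pass, led by feo (1.47), pim (1.36), borr (1.31) and tum (1.29). The cell cycle list had adjusted p = 1.3e-19, and adjusted p = 0.252 with an estimated correlation. Known roles of these genes lie in chromosome separation and cytokinesis. Of the 10 progenitor genes, 2 rose and 0 fell (5 and 1 adjusted over the list alone, 5 and 0 with the replicate block), and 8 did not pass, those that passed being zfh2 (1.21) and spdo (1.12). The progenitor list had adjusted p = 0.000166, and adjusted p = 0.252 with an estimated correlation. Delta was at 1.31 (adjusted p = 0.0747, 0.0174 with the replicate block), esg at 0.88 (adjusted p = 0.305, 0.00392 with the replicate block) and klu at -0.42 (adjusted p = 0.464), which did not pass. A second probe set of Delta, at a similar level, did pass, at 1.55 (adjusted p = 0.00944). Of the 14 Notch target genes, 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, 0 and 1 with the replicate block, 2 in all at an unadjusted p under 0.05), and 14 did not pass. E(spl)m3-HLH was at -0.74 (adjusted p = 0.258) and E(spl)mbeta-HLH at -0.5 (adjusted p = 0.319, 0.0415 with the replicate block). Of the enteroendocrine specification genes sc, a proneural factor, rose by 1.35, while pros was at 0.20 (adjusted p = 0.913). Of the 13 EGFR pathway genes, 0 rose and 0 fell by limma (1 and 0 adjusted over the list alone, 3 and 0 with the replicate block, 4 in all at an unadjusted p under 0.05), and 13 did not pass. Of these, aos was at 1.08 (adjusted p = 0.159, 0.00474 with the replicate block). Without RafGOF NotchDN replicate 1, Delta (adjusted p = 0.0127) and aos (adjusted p = 0.0364) passed, and aos also passed without RafGOF replicate 2 (adjusted p = 0.0377).

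Of the 23 ribosome biogenesis genes, 1 rose (5 adjusted over the list alone, 4 with the replicate block) and 22 did not pass, the passing gene being eIF6 (0.42), with a list median of 0.32. The ribosome biogenesis list had adjusted p = 1.02e-09, and adjusted p = 0.35 with an estimated correlation. Of the 47 digestive enzyme genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, 3 and 1 with the replicate block), and 45 did not pass, namely Jon25Biii and epsilonTry (0.80). The digestive enzyme list had adjusted p = 0.0165, and adjusted p = 0.91 with an estimated correlation. Without RafGOF replicate 4 (adjusted p = 0.230) or RafGOF NotchDN replicate 1 (adjusted p = 0.305) the digestive enzyme list was lost. In other lists the single passing members were Pal1 (-0.56) and hh (-1.27), besides sc, Drsl2 and Prx6c. With the replicate block 3 further lists passed downward, COPI (adjusted p = 0.0191), enterocyte identity (adjusted p = 0.0191) and visceral muscle (adjusted p = 0.0191). The oxidative phosphorylation list passed upward in that fit (adjusted p = 0.0344). With the block and an estimated correlation no list passed (lowest adjusted p = 0.273). The lowest adjusted p among the 26 lists that did not pass was 0.0522.

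The counts for NotchDN over RafGOF depended on single arrays and on the fit. They were 323 higher and 469 lower with the replicate block, 19 and 8 with only the 8 arrays compared, and 99 and 30 without the 4 arrays numbered 2. The count higher was 73 without RafGOF replicate 3 and 72, 68 and 79 without RafGOF NotchDN replicates 2, 3 and 4. The count lower was 39 and 29 without RafGOF replicates 2 and 3, and 41 and 36 without RafGOF NotchDN replicates 2 and 3. The number of lists passing was 10 without RafGOF replicate 1, 10 without RafGOF NotchDN replicate 2 and 8 without RafGOF NotchDN replicate 3. Lists gained with single arrays left out were COPI, enterocyte identity, matrix and integrin, enteroendocrine specification and heat shock. Oxidative phosphorylation, ribosomal protein, visceral muscle and the Wnt, Hedgehog and BMP list were gained as well (adjusted p from 0.000566 to 0.0482 over these lists). Of the 21 named genes that passed, Drsl2, Jon25Biii, Pal1, Pen, borr, eIF6, epsilonTry, hh and tum lost their call when single arrays were left out, with adjusted p up to 0.172. The number lost was 8 without RafGOF NotchDN replicate 2 or RafGOF NotchDN replicate 3, 7 without RafGOF replicate 3, 6 without RafGOF replicate 2 or RafGOF replicate 4, 5 without RafGOF replicate 1 or RafGOF NotchDN replicate 4 and 2 without RafGOF NotchDN replicate 1. With only the 8 arrays compared, 17 of the 21 lost their call. Without the 4 arrays numbered 2 (chosen after seeing the data) the oxidative phosphorylation (adjusted p = 0.025) and ribosomal protein (adjusted p = 0.031) lists passed upward.

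RafGOF with NotchIC was compared with RafGOF alone to ask what active Notch changed in RafGOF midguts. Of the cell cycle genes 16 of 32 fell, and of the ribosome biogenesis genes 8 of 23. The 3 mannosidase genes LManIII, LManV and LManVI rose, although the calls of the last 2 were lost when single arrays were left out. Pen fell by 3.12 ± 0.373 (log2, SE, n = 4 arrays per group), from 8.67 ± 0.63 (SD) to 5.55 ± 0.59, beside 5.21 ± 0.46 in wild type. The largest rises were LManIII (5.03), Drsl2 (4.27), Srg2 (2.93), LManVI (2.35) and LManV (2.32), and the largest falls were Pen (-3.12), Cks30A (-2.57), borr (-2.17), cmet (-2.01) and jumu (-1.98). Of these, Drsl2 rose with NotchDN over RafGOF as well. In all, 201 probe sets were higher and 239 lower, 90 and 81 of them by at least 2-fold. The share higher among the calls turned to 54.8% with each array centred on its median, and was 35.9% with a further quantile normalisation.

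Of the 32 cell cycle genes, 16 fell (29 adjusted over the list alone) and 16 did not pass, led by borr, Incenp (-1.87), CycB (-1.76) and feo (-1.72). The cell cycle list had adjusted p = 1.58e-28, and adjusted p = 0.142 with an estimated correlation. Of the 23 ribosome biogenesis genes, 0 rose and 8 fell (0 and 13 adjusted over the list alone, 1 and 14 with the replicate block), and 15 did not pass, led by Nopp140 (-0.85), Fib (-0.74), Nph (-0.69) and Nop60B (-0.68). The ribosome biogenesis list had adjusted p = 1.08e-10, and adjusted p = 0.192 with an estimated correlation. Of the 10 progenitor genes, 0 rose and 1 fell (1 and 4 adjusted over the list alone, 1 and 3 with the replicate block), and 9 did not pass, the passing gene being esg (-1.26). The progenitor list had adjusted p = 0.0124, and adjusted p = 0.339 with an estimated correlation. Delta was at -0.96 (adjusted p = 0.177) and klu, an enteroblast factor, at 0.66 (adjusted p = 0.0683, 0.00448 with the replicate block). The second probe set of Delta passed here too, at -1.52 (adjusted p = 0.00711). Of the 14 Notch target genes, 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, 2 and 0 with the replicate block, 2 in all at an unadjusted p under 0.05), and 14 did not pass. E(spl)mbeta-HLH was at 0.46 (adjusted p = 0.287, 0.0466 with the replicate block) and E(spl)m3-HLH at -0.07 (adjusted p = 0.985). Of the secretory lineage, sc (-1.04) and AstC (-1.03) fell, AstC being an enteroendocrine peptide, and pros was at -0.34 (adjusted p = 0.447). Of the 20 enteroendocrine peptide genes, 1 fell (3 adjusted over the list alone, 4 with the replicate block) and 19 did not pass. The enteroendocrine peptide list had adjusted p = 0.0124, and adjusted p = 0.468 with an estimated correlation. It was lost without RafGOF replicate 4 (adjusted p = 0.123) and without RafGOF NotchIC replicate 2 (adjusted p = 0.104). The EGFR ligand spi fell by 0.78, and aos was at -0.30 (adjusted p = 0.866).

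Of the 47 digestive enzyme genes, 5 rose (5 adjusted over the list alone, 8 with the replicate block) and 42 did not pass, namely LManIII, LManVI, LManV, Jon25Biii (2.16) and Mal-B2 (1.03). The digestive enzyme list had adjusted p = 0.00199, and adjusted p = 0.56 with an estimated correlation. Without RafGOF replicate 4 the digestive enzyme list was lost (adjusted p = 0.115). Of the 18 lipolysis and fatty acid oxidation genes, 3 rose and 0 fell (5 and 1 adjusted over the list alone, 5 and 1 with the replicate block), and 15 did not pass, namely whd (0.78), Acox57D-d (0.76) and yip2 (0.59). The lipolysis and fatty acid oxidation list had adjusted p = 0.00021, and adjusted p = 0.142 with an estimated correlation. Of the 16 antimicrobial and IMD genes, 1 rose (1 adjusted over the list alone) and 15 did not pass, the passing gene being Drsl2, with a list median of 0.63. The antimicrobial and IMD list had adjusted p = 5.58e-06, and adjusted p = 0.192 with an estimated correlation. In lists that did not pass, the single passing members besides sc and spi were Prx6c (-1.33), ex (-0.76) and Pxn (0.62).

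A further 5 lists passed upward in NotchIC over RafGOF although none of their members passed by limma. Of the 16 visceral muscle genes, 0 passed by limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05). The list had adjusted p = 0.0165, and adjusted p = 0.468 with an estimated correlation, and the call was lost without RafGOF replicate 1 (adjusted p = 0.0573), RafGOF replicate 3 (adjusted p = 0.152) or RafGOF NotchIC replicate 4 (adjusted p = 0.0980). Of the 10 Malpighian tubule genes, 0 rose and 0 fell by limma (2 and 0 adjusted over the list alone, 2 and 1 with the replicate block, 4 in all at an unadjusted p under 0.05), and 10 did not pass. The list had adjusted p = 0.0188, and adjusted p = 0.565 with an estimated correlation, lost without RafGOF replicate 1 (adjusted p = 0.0952), RafGOF replicate 4 (adjusted p = 0.0872) or RafGOF NotchIC replicate 2 (adjusted p = 0.404). Of the 8 trachea genes, 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, 1 and 0 with the replicate block, 1 in all at an unadjusted p under 0.05), and 8 did not pass. The list had adjusted p = 0.0305, and adjusted p = 0.192 with an estimated correlation, lost without RafGOF replicate 2 (adjusted p = 0.0941), RafGOF replicate 3 (adjusted p = 0.0728) or RafGOF NotchIC replicate 2 (adjusted p = 0.104). Of the 31 V-ATPase genes, 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, 2 and 0 with the replicate block, 7 in all at an unadjusted p under 0.05), and 31 did not pass. The list had adjusted p = 0.0155, and adjusted p = 0.468 with an estimated correlation, lost without RafGOF replicate 4 (adjusted p = 0.105) or RafGOF NotchIC replicate 2 (adjusted p = 0.0912). Of the 13 gut region genes, 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, 2 and 1 with the replicate block, 5 in all at an unadjusted p under 0.05), and 13 did not pass. The list had adjusted p = 0.0142, and adjusted p = 0.3 with an estimated correlation, lost without RafGOF replicate 1 (adjusted p = 0.0600) or RafGOF NotchIC replicate 2 (adjusted p = 0.0912). The lowest adjusted p among the 18 lists that did not pass was 0.151. Of these, the EGFR pathway list passed without RafGOF replicate 1 (adjusted p = 0.0178) and the glycolysis list without RafGOF NotchIC replicate 4 (adjusted p = 0.0289).

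The counts for NotchIC over RafGOF also depended on single arrays and on the fit. They were 576 higher and 656 lower with the replicate block, 91 and 121 with only the 8 arrays compared, and 53 and 61 without the 4 arrays numbered 2. The count higher was 96 without RafGOF replicate 2 and also 96 without RafGOF replicate 3, and 110, 107 and 106 without RafGOF NotchIC replicates 1, 2 and 3. The count lower was 105 without RafGOF replicate 2, RafGOF replicate 3 or RafGOF NotchIC replicate 2, and 131 without RafGOF NotchIC replicate 3. With RafGOF NotchIC replicate 2 left out, 7 lists passed in place of 12. Without all 4 arrays numbered 2 (chosen after seeing the data) the Notch target list passed upward (adjusted p = 0.0377), while the Malpighian tubule (adjusted p = 0.0937) and trachea (adjusted p = 0.183) lists did not pass. Of the 29 named genes that passed, Acox57D-d, AstC, Jon25Biii, LManV, LManVI, Mal-B2, Nop60B, Nph, Prx6c, Pxn, esg, ex, sc, spi and whd lost their call when single arrays were left out, with adjusted p up to 0.167. The number lost was 13 without RafGOF replicate 3 or RafGOF NotchIC replicate 2, 12 without RafGOF replicate 2, 9 without RafGOF NotchIC replicate 1 or RafGOF NotchIC replicate 3, 7 without RafGOF replicate 4, 6 without RafGOF NotchIC replicate 4 and 4 without RafGOF replicate 1.

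**Figure D4:**
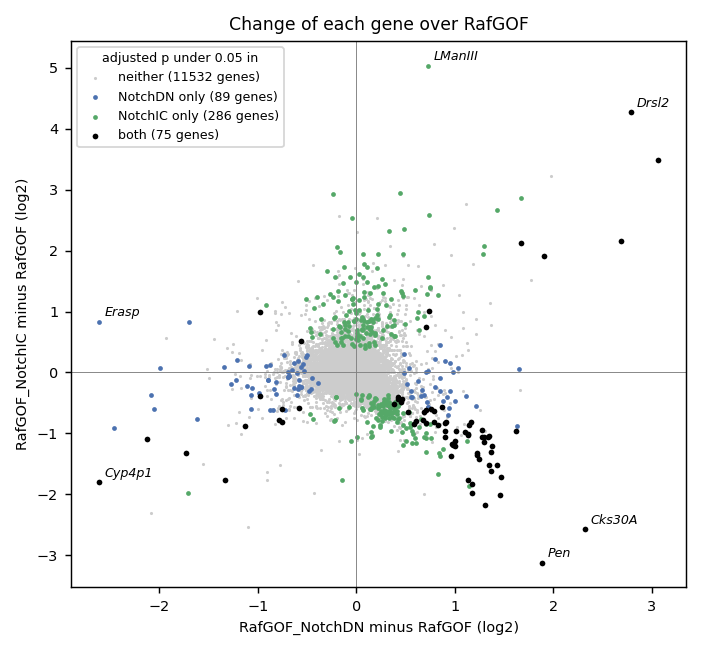
Change over RafGOF (log2) of each of the genes with one representative probe set, with NotchDN on the horizontal and NotchIC on the vertical axis, coloured by the comparison in which the gene passed. Of the 75 genes that passed in both, 58 changed in opposite directions.

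RafGOF with NotchDN was compared with RafGOF with NotchIC to set blocked against active Notch directly. Higher with NotchDN were 29 of 32 cell cycle, 15 of 23 ribosome biogenesis and 5 of 10 progenitor genes. Higher with NotchIC were 4 of 18 lipolysis and fatty acid oxidation genes and the mannosidase genes LManIII, LManV and LManVI, of which Acsf2, Lip4, bmm, LManV and LManVI lost their calls when single arrays were left out. Pen differed by 5.01 ± 0.373 (log2, SE, n = 4 arrays per group), a 32.2-fold difference. Delta was at 9.22 ± 0.82 (SD, n = 4) with NotchDN and at 6.96 ± 0.5 with NotchIC. The genes most raised with NotchDN over NotchIC were Pen (5.01), Cks30A (4.90), borr (3.48), cmet (3.47) and feo (3.19), and those most lowered were LManIII (-4.30), Erasp (-3.44), Srg2 (-3.16), cGlr1 (-2.50) and Bcat (-2.20). In all, 870 probe sets were higher with NotchDN and 767 lower, 266 and 168 of them by at least 2-fold. The counts were 1542 and 1958 with the replicate block. The share higher among the calls turned to 44.4% with each array centred on its median, and was 61.7% with a further quantile normalisation. Without RafGOF NotchDN replicate 3 the count lower was 402, and without RafGOF NotchIC replicate 3 it was 442.

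Of the 32 cell cycle genes, 29 were higher (29 adjusted over the list alone) and 3 did not pass, borr and feo being followed by Incenp (3.01) and pim (2.98). The cell cycle list had adjusted p = 1.84e-31, and adjusted p = 0.111 with an estimated correlation. Of the 23 ribosome biogenesis genes, 15 were higher (18 adjusted over the list alone) and 8 did not pass, led by Nopp140 (1.32), Nnp-1 (1.18), Fib (1.12) and Nop56 (1.09). The ribosome biogenesis list had adjusted p = 1.02e-14, and adjusted p = 0.136 with an estimated correlation. Of the 10 progenitor genes, 5 were higher and 1 was lower (7 and 1 adjusted over the list alone), and 4 did not pass, led by Delta (2.27), esg (2.14), zfh2 (1.76) and spdo (1.5). The progenitor list had adjusted p = 7.4e-05, and adjusted p = 0.136 with an estimated correlation. The progenitor gene lower with NotchDN was klu (-1.09). Of the 14 Notch target genes, 2 were lower (2 adjusted over the list alone) and 12 did not pass, namely E(spl)mbeta-HLH (-0.96) and E(spl)m7-HLH (-0.65). The Notch target list had adjusted p = 0.165, and adjusted p = 0.618 with an estimated correlation, and did not pass. E(spl)m3-HLH was at -0.67 (adjusted p = 0.123). Of the 13 EGFR pathway genes, 4 were higher and 1 was lower (4 and 1 adjusted over the list alone), and 8 did not pass, namely aos (1.39), sty (1.32), Egfr (1.08), spi (1.0) and aop (-0.62). The EGFR pathway list had adjusted p = 0.156, and adjusted p = 0.618 with an estimated correlation, and did not pass. Of the secretory lineage, sc (2.39) and AstC (1.20) were higher with NotchDN, and pros was at 0.53 (adjusted p = 0.0523, 0.0189 with the replicate block). The call of pros was gained without RafGOF NotchDN replicate 1 (adjusted p = 0.0427) or RafGOF NotchIC replicate 4 (adjusted p = 0.0139).

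Of the 18 lipolysis and fatty acid oxidation genes, 4 were lower (7 adjusted over the list alone, 9 with the replicate block) and 14 did not pass, namely Acsf2 (-1.18), yip2 (-0.67), Lip4 (-0.60) and bmm (-0.53). The lipolysis and fatty acid oxidation list had adjusted p = 0.00436, and adjusted p = 0.194 with an estimated correlation. Of the 16 visceral muscle genes, 2 were lower (3 adjusted over the list alone, 8 with the replicate block) and 14 did not pass, namely tn (-0.61) and Zasp66 (-0.52). The visceral muscle list had adjusted p = 0.00239, and adjusted p = 0.307 with an estimated correlation. Of the 16 antimicrobial and IMD genes, 2 were lower (2 adjusted over the list alone, 5 with the replicate block) and 14 did not pass, namely imd (-0.51) and PGRP-LE (-0.40). The antimicrobial and IMD list had adjusted p = 0.00596, and adjusted p = 0.397 with an estimated correlation. Of the 10 enterocyte identity genes, 1 was higher and 1 was lower (1 and 6 adjusted over the list alone, 1 and 6 with the replicate block), and 8 did not pass, namely mag (1.88) and Ssk (-0.73). The enterocyte identity list had adjusted p = 0.0274, and adjusted p = 0.194 with an estimated correlation. Its mean signal was lower with NotchDN (10.82) than with NotchIC (11.13), opposite to mag. Without RafGOF NotchDN replicate 1 (adjusted p = 0.0614) or RafGOF NotchIC replicate 4 (adjusted p = 0.0539) the enterocyte identity list was lost. Of the 41 genes in the ribosomal protein list, 1 was higher (1 adjusted over the list alone, 3 with the replicate block) and 40 did not pass, the passing gene being RpLP0-like (0.70). The ribosomal protein list had adjusted p = 0.0274, and adjusted p = 0.627 with an estimated correlation. It was lost without RafGOF NotchDN replicate 3 (adjusted p = 0.0555), RafGOF NotchDN replicate 4 (adjusted p = 0.0804) or RafGOF NotchIC replicate 2 (adjusted p = 0.116). Of the 47 digestive enzyme genes, 1 was higher and 4 were lower (2 and 4 adjusted over the list alone, 5 and 6 with the replicate block), and 42 did not pass, namely LManIII, LManV (-1.99), LManVI (-1.86), Mal-B2 (-1.04) and epsilonTry (0.58). The digestive enzyme list had adjusted p = 0.566, and adjusted p = 0.884 with an estimated correlation, and did not pass. Of the 20 matrix and integrin genes, 2 were higher and 3 were lower (5 and 6 adjusted over the list alone, 5 and 6 with the replicate block), and 15 did not pass, namely Mmp2 (-1.59), LanB1 (1.17), Itgbn (-0.97), Ppn (-0.74) and trol (0.64). In the remaining lists, none of which passed, the passing genes were FASN2 (-1.12), Lpin (-0.57), hh (-1.08), ZnT35C (-0.96), dve (-0.73), Gasp (-0.61), chinmo (-0.51), Tpi (-0.41) and sav (-0.41). Single arrays left out brought a pass for the EGFR pathway, glycolysis, gut region, Malpighian tubule and V-ATPase lists (adjusted p from 0.0191 to 0.0493). With the replicate block the gut region list (adjusted p = 0.0399) and the Malpighian tubule list (adjusted p = 0.0333) passed as well, both downward, but with the block and an estimated correlation no list did (lowest adjusted p = 0.175). On other probe sets at log2 5 or above the changes of 4 named genes did not pass, which were sty (0.92, adjusted p = 0.0693), klu (0.04, adjusted p = 0.88), dve (0.18, adjusted p = 0.386) and trol (0.34, adjusted p = 0.333, on the brightest of its others). For trol a further probe set at such a level did pass (1.30, adjusted p = 0.0156).

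Of the 59 named genes that passed between the Notch groups, 21 lost their call when single arrays were left out, with adjusted p up to 0.159. These were Acsf2, E(spl)m7-HLH, Egfr, FASN2, Gasp, LManV, LManVI, Lip4, Lpin, PGRP-LE, Ssk, Zasp66, ZnT35C, bmm, chinmo, dve, epsilonTry, hh, mag, sav and trol. The number lost was 20 without RafGOF NotchDN replicate 3, 19 without RafGOF NotchIC replicate 3, 14 without RafGOF NotchIC replicate 1, 13 without RafGOF NotchDN replicate 2, 12 without RafGOF NotchDN replicate 4, 11 without RafGOF NotchIC replicate 2 and 8 without RafGOF NotchDN replicate 1 or RafGOF NotchIC replicate 4.

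The changes with NotchDN and with NotchIC were both measured against the same RafGOF arrays, which by itself pushes their correlation upward. Across probe sets, which are not independent replicates, the changes correlated at -0.0169, against a mean of 0.504 in 20 simulated data sets with no effect, and their covariance was -0.00124 against 0.0166. With noise drawn independently for each array, the sharing alone fixes that simulated correlation. The replicate numbers were not kept, and deviations shared by number cancel between groups, so the simulated covariance may be too high. With the RafGOF arrays split so that each change had its own reference arrays, the correlation lay between -0.338 and -0.149. Where same-numbered arrays deviate together, however, the 2 parts of the split deviate in opposite directions. This by itself pushes the correlation downward, and no simulated value was made for the split. Of the probe sets called in both comparisons, 68 were higher with NotchDN and lower with NotchIC, where 1.54 would be shared by independent lists. A further 2 were lower with NotchDN and higher with NotchIC (0.889 by independent lists), 11 were higher in both (1.30) and 15 lower in both (1.06). For the 26 that changed in the same direction the shared RafGOF arrays make independent lists too low a comparison, and simulations with these arrays shared and an effect in 1 comparison only gave a mean of 11.6 and at most 18. In the order given the 4 counts were 141, 17, 28 and 37 with the replicate block, where such simulations gave a mean of 29.8 and at most 40 in the same direction. Among the named genes, Pen, Cks30A, CycB, borr, cmet, eIF6, feo, jumu, pim, sc and tum were higher with NotchDN and lower with NotchIC. Drsl2, Jon25Biii and Cyp6a9 were higher in both, and Prx6c and Cyp4p1 were lower in both. Of the 3578 probe sets called between RafGOF and wild type, 83.7% moved back toward wild type with NotchIC and 48.6% with NotchDN. The shared RafGOF arrays alone gave 60.2% in simulated data that also left out the replicate numbers, so this share may be too high as well. With separate reference arrays the shares ran from 63.6% to 87.9% for NotchIC and from 34.3% to 47.1% for NotchDN. Deviations shared by replicate number push these split shares downward by themselves.

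Both Notch groups were also compared with wild type. RafGOF with NotchDN had 2095 probe sets higher and 1741 lower, and RafGOF with NotchIC had 1408 higher and 984 lower. With the replicate block the NotchIC counts were 2512 higher and 1835 lower, and without RafGOF NotchIC replicate 3 they were 904 and 600. Of the 32 cell cycle genes, 29 were higher than in wild type with NotchDN and 7 with NotchIC (30 and 9 adjusted over the list alone). With the replicate block 11 were higher with NotchIC. Of the 47 digestive enzyme genes, 25 were lower with NotchDN and 22 with NotchIC (29 and 27 adjusted over the list alone).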

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

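The tests of the digestive enzyme genes and of the replicate numbers in this part were chosen after the results were seen, and those of the shared RafGOF arrays and of the splits before. Of 652 sets of 4 arrays examined, 40 had 1 array far from the other 3 by Dixon's test, 31 for a named gene and 9 for a list mean. Chance gives about 1 in 20 sets. The array apart was numbered 1 in 17 sets, 2 in 17, 3 in 3 and 4 in 3.

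The values (log2) of these arrays are given with the range of the other 3 arrays of the group. On RafGOF replicate 1, PGRP-SC2 was at 12.11 against 10.87 to 10.95, CycE was at 6.77 against 7.55 to 7.65 and the mean of the list egfr ras mapk was at 7.8 against 8.27 to 8.35. On RafGOF replicate 2, Pen was at 9.61 against 8.27 to 8.43, ND-51L1 was at 4.78 against 5.39 to 5.51 and Egfr was at 7.54 against 6.74 to 6.75. On RafGOF replicate 4, CCHa2 was at 9.44 against 8.14 to 8.23. On RafGOF NotchDN replicate 1, betaTub60D was at 10.28 against 12.27 to 12.65, exex was at 7.54 against 9.02 to 9.22, COX7AL2 was at 6.48 against 5.94 to 6.01 and Cyp4p1 was at 7.43 against 8.11 to 8.18. Also on RafGOF NotchDN replicate 1, the mean of the list jnk stress redox was at 8.42 against 8.78 to 8.85 and the mean of the list v atpase was at 8.72 against 8.52 to 8.54. On RafGOF NotchDN replicate 4, Lip3 was at 5.11 against 4.76 to 4.81. On RafGOF NotchIC replicate 1, betaTub60D was at 11.73 against 12.45 to 12.55, cmet was at 4.2 against 3.82 to 3.87, Lip4 was at 8.12 against 7.79 to 7.84 and tn was at 8.65 against 8.31 to 8.37. Also on RafGOF NotchIC replicate 1, the mean of the list hemocyte was at 5.37 against 5.27 to 5.29. On RafGOF NotchIC replicate 2, zetaCOP was at 6.41 against 7.51 to 7.68, Oatp58Db was at 9.17 against 7.97 to 8.07, RpL34a was at 11.92 against 12.25 to 12.29 and Vha100-5 was at 11.83 against 10.4 to 10.58. Also on RafGOF NotchIC replicate 2, LManVI was at 12.83 against 10.45 to 10.73, LManV was at 13.15 against 10.37 to 10.71, jumu was at 4.17 against 4.8 to 4.92 and PGRP-LE was at 9.68 against 9.81 to 9.83. Also on RafGOF NotchIC replicate 2, Egfr was at 7.3 against 6.36 to 6.49 and the mean of the list malpighian tubule was at 9.39 against 8.39 to 8.5. On RafGOF NotchIC replicate 3, tap was at 3.3 against 3.89 to 3.96, Cht2 was at 9.5 against 8.55 to 8.7 and the mean of the list antimicrobial imd was at 9.71 against 8.8 to 8.9. On RafGOF NotchIC replicate 4, Lpin was at 9.52 against 9.87 to 9.92. On WT replicate 1, sc was at 5.14 against 5.28 to 5.3, tum was at 5.8 against 5.31 to 5.39 and the mean of the list heat shock was at 10.26 against 9.75 to 9.78. On WT replicate 2, Prestin was at 10.86 against 9.32 to 9.47, imd was at 7.45 against 7.03 to 7.07, the mean of the list lipolysis fatty acid oxidation was at 9.34 against 9.07 to 9.11 and the mean of the list ribosomal protein was at 11.64 against 11.87 to 11.88.

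The ACTIN 3' control probe set, which no comparison used, was higher than in wild type by 1.57 in RafGOF and by 1.69 in RafGOF NotchIC, with every array of these groups above every wild type array (10.71 to 11.57). In RafGOF NotchDN it was at 12.70 to 13.0 on 3 arrays, above wild type as well, and at 11.47 on replicate 1, within the range of wild type.

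Deviations of same-numbered arrays correlated between groups, though 8 of these 24 correlations were below the highest with another number, none of them for the arrays numbered 2. A candidate explanation is RNA labelling in batches that follow the replicate number. The 3' minus 5' signal of the added poly-A control RNAs, which do not come from the flies, differed between the numbers (exact permutation p = 0.00203, 13824 permutations within groups). This shows that the added controls differed, phe and lys being higher and thr mostly lower on the arrays numbered 2. It shows neither the step at fault nor that the fly genes moved. Among fly control transcripts, the 3' minus 5' signal of GAPDH was 1.42 to 2.21 on the arrays numbered 2 and 1.11 to 1.33 on the others. For ACTIN (1.11 to 1.95 against 0.7 to 2.49) and eIF-4a (1.26 to 2.24 against 1.18 to 2.72) the ranges overlapped. Carry-over of Malpighian tubule tissue stays open as well, since the tubule list had the largest mean deviation of the 30 lists on the arrays numbered 2 (0.446, from 0.32 to 0.705), although other lists deviated there too, ribosome biogenesis by 0.245. Different crosses or days of dissection stay open, and no biological explanation was tested.

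Digestive enzyme genes were lower in RafGOF than in wild type, with a median of -1.46. A smaller share of enterocytes would lower genes confined to enterocytes by about as much, if nothing else changed them. Of the 10 measured enterocyte identity genes 1 (mag) fell that far, and their median was 0.21. The list was mixed, with mag (-1.70) and Smvt (-0.75) called lower and Ssk and cora (0.89 each) called higher. Whether its members are confined to enterocytes was not tested, so a smaller share is not excluded. The counts of digestive enzyme genes lower with the replicate block (34) and without it (31) decide nothing, since each group holds each number once. For the same reason a difference between the numbers adds alike to both groups. Lower expression of these enzymes within enterocytes stays open as well, and no other technical explanation was tested for this pattern.

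A set of 26 probe sets changed in the same direction with NotchDN and with NotchIC over RafGOF. Shared RafGOF arrays gave at most 18 such probe sets in 20 simulations with an effect in 1 comparison only, which is below 26 but not by the factor of 2 set beforehand. There were 65 with the replicate block, and at most 40 in 20 simulations that kept the replicate numbers (chosen after the results were seen), again short of that factor. A shift of the RafGOF flies alone would place both Notch groups nearer to wild type, which held for 73.1% of these probe sets. A partial reversal of the effect of Raf would do the same, so these explanations cannot be told apart with 1 RafGOF group.

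For the count of called probe sets in each comparison, all 35 splits of its 8 arrays into 4 and 4 were fitted. Only the real split, 1 of 35, gave as many calls in each of the 6 comparisons. A chance split can be excluded at that share only where the arrays are not paired by number. The real count and the highest other were 3578 and 0 for RafGOF minus wild type, 204 and 97 for NotchDN over RafGOF, 440 and 4 for NotchIC over RafGOF, and 1637 and 1 between the Notch groups. They were 3836 and 0 for NotchDN minus wild type and 2392 and 14 for NotchIC minus wild type. By the minimum of 0.1 the numbers paired the arrays in 5 of the comparisons. They fell short of this for NotchIC minus wild type by 1 of its 4 correlations (0.0489). That minimum is weak evidence of pairing for some numbers. Replicate 3 of NotchIC and RafGOF correlated at 0.104, and at up to 0.441 with another number. For replicate 4 of NotchDN and NotchIC these values were 0.157 and 0.445. Only 8 splits part all same-numbered pairs, while the other 27 keep some of them together. The real split was 1 of these 8, which are too few for a share under 0.05, and the highest other count among them was 4 for NotchIC over RafGOF and 0 for the other 5 comparisons.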

How the results depend on the processing

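Among the called lists and the named genes that passed, none changed direction under any alternative. The direction of every called probe set was not checked under every alternative. Many counts moved by more than 1.5 times, most of all for the Notch groups over RafGOF. With array weights, the counts of probe sets were 3279 higher and 2850 lower for RafGOF minus wild type, 655 higher and 657 lower for RafGOF NotchDN minus RafGOF, 620 higher and 706 lower for RafGOF NotchIC minus RafGOF, 1507 higher and 1704 lower for RafGOF NotchDN minus RafGOF NotchIC, 3202 higher and 2864 lower for RafGOF NotchDN minus wild type and 2165 higher and 1499 lower for RafGOF NotchIC minus wild type. With the replicate block, the counts of probe sets were 3220 higher and 2289 lower for RafGOF minus wild type, 323 higher and 469 lower for RafGOF NotchDN minus RafGOF, 576 higher and 656 lower for RafGOF NotchIC minus RafGOF, 1542 higher and 1958 lower for RafGOF NotchDN minus RafGOF NotchIC and 2512 higher and 1835 lower for RafGOF NotchIC minus wild type. With the replicate block, the counts of gene lists were 8 called for RafGOF NotchDN minus RafGOF. At an adjusted p under 0.01, the counts of probe sets were 1368 higher and 928 lower for RafGOF minus wild type, 56 higher and 22 lower for RafGOF NotchDN minus RafGOF, 61 higher and 84 lower for RafGOF NotchIC minus RafGOF, 501 higher and 288 lower for RafGOF NotchDN minus RafGOF NotchIC, 1137 lower for RafGOF NotchDN minus wild type and 710 higher and 473 lower for RafGOF NotchIC minus wild type. At an adjusted p under 0.05 and a change of at least 2-fold, the counts of probe sets were 552 higher and 592 lower for RafGOF minus wild type, 58 higher and 29 lower for RafGOF NotchDN minus RafGOF, 90 higher and 81 lower for RafGOF NotchIC minus RafGOF, 266 higher and 168 lower for RafGOF NotchDN minus RafGOF NotchIC, 695 higher and 673 lower for RafGOF NotchDN minus wild type and 362 higher and 356 lower for RafGOF NotchIC minus wild type. With each array centred on its median, the counts of probe sets were 77 higher for RafGOF NotchDN minus RafGOF and 145 lower for RafGOF NotchIC minus RafGOF. With only the 8 arrays compared in the fit, the counts of probe sets were 19 higher and 8 lower for RafGOF NotchDN minus RafGOF and 91 higher and 121 lower for RafGOF NotchIC minus RafGOF. Without the 4 arrays numbered 2 (chosen after seeing the data), the counts of probe sets were 30 lower for RafGOF NotchDN minus RafGOF and 53 higher and 61 lower for RafGOF NotchIC minus RafGOF. With an estimated correlation, the counts of gene lists were 0 called for RafGOF minus wild type, 0 called for RafGOF NotchDN minus RafGOF, 0 called for RafGOF NotchIC minus RafGOF and 0 called for RafGOF NotchDN minus RafGOF NotchIC. With fry, the counts of gene lists were 2 called for RafGOF NotchDN minus RafGOF and 5 called for RafGOF NotchIC minus RafGOF. With single arrays left out in turn, the counts ran over 68 to 174 higher for RafGOF NotchDN minus RafGOF, 29 to 97 lower for RafGOF NotchDN minus RafGOF, 96 to 250 higher for RafGOF NotchIC minus RafGOF, 105 to 247 lower for RafGOF NotchIC minus RafGOF, 402 to 771 lower for RafGOF NotchDN minus RafGOF NotchIC, 904 to 1601 higher for RafGOF NotchIC minus wild type, 600 to 997 lower for RafGOF NotchIC minus wild type, 3 to 10 lists called for RafGOF NotchDN minus RafGOF and 7 to 12 lists called for RafGOF NotchIC minus RafGOF. Every probe set called without the replicate block was also called with it. The calls of lists and named genes that it added are given beside their comparisons, and it removed no call. Of the named genes that did not pass, array weights called Delta (adjusted p = 0.000435), esg (adjusted p = 0.0056) and aos (adjusted p = 0.000571) in NotchDN over RafGOF. They also called Delta (adjusted p = 0.0322) and E(spl)mbeta-HLH (adjusted p = 0.0246) in NotchIC over RafGOF and pros (adjusted p = 0.0238) between the Notch groups. With the mean of all probe sets of a gene, Delta (adjusted p = 0.0176) passed in NotchDN over RafGOF, Delta (adjusted p = 0.0255) in NotchIC over RafGOF and pros (adjusted p = 0.0429) between the Notch groups. A further quantile normalisation called Delta (adjusted p = 0.0396) in NotchDN over RafGOF, and the filter on dim probe sets called pros (adjusted p = 0.0415) between the Notch groups. Centring and quantile normalisation shifted the share of higher among called probe sets by less than 10 percentage points. Centring nevertheless turned the majority in NotchIC over RafGOF, from lower to higher (54.8%), and between the Notch groups, from higher to lower with NotchDN (44.4%). The replicate block turned it too, from 59.31% to 40.78% higher in NotchDN over RafGOF and from 53.15% to 44.06% between the Notch groups. Of the named calls, 7 of 74 were lost without the arrays numbered 2 in RafGOF minus wild type, 9 of 21 in NotchDN over RafGOF, 17 of 29 in NotchIC over RafGOF and 17 of 59 between the Notch groups. With only the 8 arrays compared, 5 of 74, 17 of 21, 14 of 29 and 14 of 59 were lost in the same order. The stricter thresholds call fewer probe sets by construction, and for the other alternatives the cause was not tested. For dim probe sets the signal over background limits what can be seen.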

Other observations

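These 11 gene families were chosen after seeing the data, and all tests in this part were chosen after the results were seen. By the list test 10 of them passed in RafGOF minus wild type, 5 in NotchDN over RafGOF, 9 in NotchIC over RafGOF and 8 between the Notch groups, and with an estimated correlation none passed in any of these (lowest adjusted p = 0.108). Between RafGOF and wild type, 52 of 69 mitochondrial ribosomal protein genes were higher (median 0.48, adjusted p = 5.81e-18, and adjusted p = 0.142 with an estimated correlation). Proteasome genes were higher in 23 of 40 (adjusted p = 1.41e-06, and adjusted p = 0.142 with an estimated correlation), nucleoporin genes in 14 of 20 (adjusted p = 3.14e-07, and adjusted p = 0.142 with an estimated correlation) and origin licensing and GINS genes in 11 of 13 (adjusted p = 8.79e-07, and adjusted p = 0.142 with an estimated correlation). Families were gathered by gene symbol, and the 40 proteasome genes include related copies such as Prosbeta5R1, Prosalpha4T1 and Rpt3R. Genes of RNA polymerase I and III were higher in 7 of 14 (adjusted p = 0.00035, and adjusted p = 0.142 with an estimated correlation), and chaperonin genes in 6 of 8 (adjusted p = 0.00153, and adjusted p = 0.338 with an estimated correlation). Of 81 cytochrome P450 genes, 39 were lower and 4 higher (median -0.56, adjusted p = 1.03e-11, and adjusted p = 0.142 with an estimated correlation). UDP-glycosyltransferase genes were lower in 15 and higher in 1 of 35 (adjusted p = 1.8e-05, and adjusted p = 0.279 with an estimated correlation). Glutathione S-transferase genes were lower in 9 and higher in 4 of 34 (adjusted p = 0.0285, and adjusted p = 0.561 with an estimated correlation). Of 15 aminoacyl-tRNA synthetase genes 0 passed by limma and 4 had an unadjusted p under 0.05 (list adjusted p = 0.0285, and adjusted p = 0.577 with an estimated correlation). Of 9 immune-induced peptide genes 0 passed by limma and 0 had an unadjusted p under 0.05 (list adjusted p = 0.291, which did not pass).

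Between RafGOF with NotchDN and RafGOF with NotchIC, 22 of 69 mitochondrial ribosomal protein genes and 10 of 20 nucleoporin genes were higher with NotchDN (adjusted p = 4.46e-13 and 1.32e-10, and adjusted p = 0.28 and 0.119 with an estimated correlation). Cytochrome P450 genes were lower with NotchDN in 15 and higher in 1 of 81 (adjusted p = 6.2e-06, and adjusted p = 0.26 with an estimated correlation). Of the other families 8 of 13 origin licensing and GINS, 7 of 14 RNA polymerase I and III and 1 of 8 chaperonin genes were higher with NotchDN, 2 of 35 UDP-glycosyltransferase genes were lower, and 2 of 34 glutathione S-transferase genes were higher and 2 lower. By limma 0 proteasome, 0 aminoacyl-tRNA synthetase and 0 immune-induced peptide genes passed there, with 4, 1 and 0 at an unadjusted p under 0.05. Over RafGOF, at most 5 members of a family passed with NotchDN and at most 10 with NotchIC, in both cases of cytochrome P450. The 9 immune-induced peptide genes had a median of 1.44 in NotchIC over RafGOF (adjusted p = 5.49e-05, and adjusted p = 0.271 with an estimated correlation), while 0 of them passed by limma at an adjusted p under 0.05 and 6 had an unadjusted p under 0.05. With median centring and with quantile normalisation the family medians kept their sign in these comparisons, except those of aminoacyl-tRNA synthetase and chaperonin genes in NotchDN over RafGOF. The 3' minus 5' signal of the fly control transcripts differed between groups by -0.0726 to 0.226, with SDs within groups of 0.179 to 0.515 (exact permutation p from 0.286 to 1, all adjusted to 1).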
